A study of Arabidopsis thaliana with 39 samples.

How the data were processed

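The RNA data were 36 poly(A)-enriched libraries of whole Arabidopsis thaliana seedlings, 5 days old and grown on solid medium, sequenced by the BGISEQ-500 protocol, per the labels. The labels give 4 genotypes, 3 treatments and 3 replicates of each of the 12 groups. The genotypes were wild type (WT), the glyoxalase I mutant glyI2, and 2 lines labelled 35S::GLYI2 and 35S::GLYII4, called here OE1 (line #1) and OE5 (line #5). The treatments were mock, 100 mM NaCl for 12 h and 200 µM methylglyoxal (MG) for 12 h. Labels named no separate cultures, days or batches, so the p-values measure the spread between these libraries, which may in part be technical. A further 3 chromatin samples of the series were not analysed here.

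Each library came with a count of reads per gene and an FPKM value per gene, both computed by the authors and used as deposited. Reads had been aligned with HISAT2 2.0.4 and counted with HTSeq against TAIR10, per the submitters' processing notes, which also name SICER and ChIPseeker. Whether counting used the strand is not given in the sources used here, so values of genes that overlap another gene, or have an antisense partner, are uncertain. The deposited counts were whole numbers for 32678 genes and summed to between 21024878 and 22383131 per library. All 279 chloroplast and mitochondrial genes were at 0 in every library. The authors' FPKM values were used only to work back to the gene length they imply, for the 18523 genes where it could be computed, and lengths from different libraries deviated by at most 0.0787%. Members of the gene lists carry the names they were listed under, and other genes were named by locus identifier from a reference gene table of assembly TAIR10.1, with 31912 identifiers matched. Of the listed genes 412 had a matching name in that table and 23 had no name there, GLYI2 (AT1G08110) and GLYI6 (AT1G67280) among them. Another 7, all of the glyoxalase list, have a different name there and were kept, among them GLYII4 (AT2G43430), which the table calls GLX2-1. That assembly is not named in the labels, so no coordinates are given.

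Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, after TMM normalization and edgeR's default expression filter, which left 20748 genes. The robust fit took in all 36 libraries, so that the 12 groups shared an estimate of the spread, without a replicate term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Standard errors (SE) of log2 fold changes were derived from the F statistic. Levels are TMM-scaled counts per library size (CPM in edgeR), as mean ± SD over the 3 libraries of a group. Every adjusted p of a gene is edgeR's unless another tool is named. The correlation of a library with gene length is Spearman's. It was taken over genes, between the implied length and the library's log2 CPM minus the gene's mean over the 36 libraries. The design gave 17 comparisons: NaCl or MG against mock in each genotype, each line against WT under mock, and the differences in response between each line and WT. Those differences were tested as interaction terms.

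Altogether 27 gene lists with 444 members were fixed before the data were examined, and 423 members were tested. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with its preset inter-gene correlation, adjusted over the lists within a comparison. The test was run again with an estimated correlation, with which 21 of 459 list tests were called against 112 with the preset value. For each list the members called over all genes tested are given, and also the number adjusted over the list alone. The size of a whole response was compared by a score per library, the mean log2 CPM of the genes raised minus that of the genes lowered in both genotypes not compared. Differences in that score had an exact two-sided permutation test over 400 relabellings, adjusted over 6 tests. Comparisons that share the WT mock libraries were set beside 20 simulations of unchanged groups.

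The rule for named genes was also fixed in advance. It covers every glyoxalase family member in every comparison. It adds up to 10 raised and 10 lowered genes with the largest called log2 changes per WT comparison (5 and 5 elsewhere), with an average log2 CPM of at least 1 and no overlap between the groups' values, a condition not set for differences in response. It also adds up to 4 members of each list by adjusted p. The genes printed were chosen from those the rule allows after their values were seen, so they lean towards large changes.

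Alternatives were DESeq2 1.42.0, RLE scaling, no expression filter, a fit on the compared groups only, the replicate number as a block, and leaving out each library in turn. Leaving out 7 libraries with low CCA1 was added after the data were seen, as were the fits on the compared groups and without the filter for named genes and overlaps. Replicate numbers were checked for pairing by correlating the deviations of same-numbered libraries from their group means. All 3 pairs correlated above 0.1 in 3 comparisons: OE5 NaCl against mock (0.131 to 0.734), glyI2 MG against mock (0.193 to 0.511) and OE5 MG against mock (0.197 to 0.555).

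The fits were tested on simulated data in which 200 genes of 20748 were changed. For WT NaCl against WT mock, edgeR recovered 34% of the genes changed 2-fold and 76% of those changed 4-fold, with 4 false calls among 114, and DESeq2 recovered 45% and 87% with 19 false calls among 151. For the MG response of glyI2 against WT the shares were 8% and 46% by edgeR and 12% and 55% by DESeq2. With 3 libraries per group, small differences in response are therefore often missed. A simulated list of 20 raised genes was called and 0 of 26 unchanged lists were. The simulated genes varied independently of each other. These lists therefore cannot show whether the preset inter-gene correlation limits false list calls in the real data. No replicate pair agreed within sampling noise, since the chi-square per gene between replicates ran from 14.9 to 265.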

Results

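RNA from Arabidopsis thaliana wild type (WT), the glyI2 mutant and the libraries labelled OE1 and OE5, whose labels name 35S::GLYI2 and 35S::GLYII4, was sequenced. Plants had been given mock treatment, 100 mM NaCl for 12 h or 200 µM methylglyoxal (MG) for 12 h, with 3 libraries in each of the 12 groups. The first 3 principal components of the 36 libraries held 36.1%, 15.8% and 15% of the variance. The biological coefficient of variation was 28.3%. Levels are given in CPM (mean ± SD, n = 3 libraries) and changes as log2 fold change ± SE with n = 3 libraries per group.

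GLYI2 (AT1G08110), which encodes a glyoxalase I, stood at 61.3 ± 8.23 CPM in WT mock and at 7.93 ± 2.25 in glyI2 mock (−2.95 ± 0.23, adjusted p = 4.1e-09). In the libraries labelled OE1 and OE5 it was not raised, at 28.1 ± 6.98 and 51.3 ± 6.72 CPM in mock, which does not match the 35S::GLYI2 of their labels. Whether reads of a modified transgene were missed by the counts is not known. The fall of GLYI2 in OE1 mock (−1.13 ± 0.22, adjusted p = 0.0358) was lost without WT mock replicate 1 (0.0936), 2 (0.152) or 3 (0.43), without OE1 mock replicate 1 (0.119) or 2 (0.796), with RLE scaling (0.0532) and with the compared groups alone (0.162). In WT, GLYI2 did not pass the test after NaCl (−0.24 ± 0.21, adjusted p = 0.622) or MG (−0.06 ± 0.21, adjusted p = 0.963).

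GLYII4 (AT2G43430), listed here as a glyoxalase II family member, stood at 10.7 ± 1.53 CPM in WT mock, 11.8 ± 2.09 in glyI2 mock, 31 ± 4.08 in OE1 mock and 32.1 ± 5.99 in OE5 mock. It was higher than WT in OE1 mock (1.53 ± 0.25, adjusted p = 0.00664) and in OE5 mock (1.58 ± 0.25, adjusted p = 0.00494). The OE1 call was lost without WT mock replicate 1 (0.0936) or 2 (0.143), and the OE5 call without WT mock replicate 1 (0.1) or 2 (0.0931). With the compared groups alone both were lost (0.0766 in OE1 and 0.201 in OE5). After MG, GLYII4 reached 300 ± 74.3 CPM in OE1 and 265 ± 91 in OE5, against 11.7 ± 1.75 in WT and 11.3 ± 1.49 in glyI2. In WT it did not pass the test after MG (0.12 ± 0.25, adjusted p = 0.922) or NaCl (−0.11 ± 0.25, adjusted p = 0.892).

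**Figure D1:**
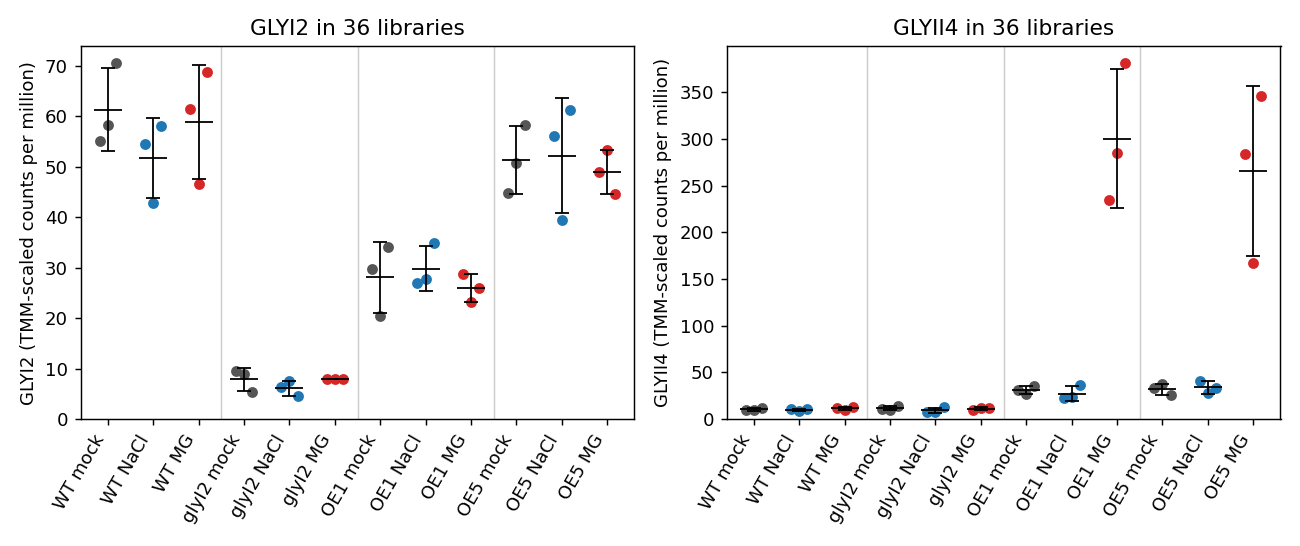
Levels of GLYI2 and GLYII4 in TMM-scaled CPM; each point is 1 of 36 libraries, the short line is the mean of 3 and the whiskers are the SD. GLYI2 is low in the glyI2 libraries and GLYII4 is highest in the OE1 and OE5 libraries treated with MG.

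Without treatment few genes were called between the lines and WT. At unadjusted p under 0.05 there were 359 genes in glyI2, 1907 in OE1 and 720 in OE5, where 1037 are expected if no gene differs. Only OE1 lay above this number, and the others lay under it, so it is a rough guide. Without the 7 libraries low in CCA1 described below the counts were 167, 3005 and 144. OE1 mock replicates 1, 2 and 3 lay at −49.4, −64.6 and 17.1 on the second principal component, against −15.6 to −6.7 in WT mock. Whether the excess in OE1 comes from the line or from such differences between libraries was not tested. In glyI2 mock 9 genes were called, 5 higher and 4 lower, out of 20748 tested. QQS, an orphan gene tied to starch content, was at 30.2 ± 5.08 CPM against 0.537 ± 0.227 (5.8 ± 0.29, adjusted p = 7.9e-14). AT5G35935 was higher (2.63 ± 0.27, adjusted p = 1.28e-06), and the microRNA gene MIR167a was at 0.3 ± 0.125 CPM against 14.7 ± 9.19 (−5.63 ± 0.59, adjusted p = 1.28e-06). MIR167a was also lower in OE1 mock (−5.42 ± 0.58, adjusted p = 4.78e-06) and in OE5 mock (−5.29 ± 0.57, adjusted p = 5.44e-06), the last a call lost with the compared groups alone (0.2). DESeq2 called 10 genes in glyI2 mock, and edgeR with the compared groups alone called 5.

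In OE1 mock 11 genes were called (8 higher, 3 lower; 10 by DESeq2). AT5G35935 (2.72 ± 0.27, adjusted p = 1.96e-06) and AT2G41640 (1.51 ± 0.2, adjusted p = 0.00018) were higher. The retroelement SADHU3-2 was higher (2.53 ± 0.45, adjusted p = 0.0154), a call lost without WT mock replicate 1 (0.0915), 2 (0.263) or 3 (0.112) or OE1 mock replicate 1 (0.0946) or 2 (0.11). The count of genes fell from 11 to 4 without WT mock replicate 1, 4 without replicate 2 and 5 without replicate 3, and to 7 and 5 without OE1 mock replicates 1 and 2. With the compared groups alone it was 3, and AT2G41640 (0.161) and SADHU3-2 (0.161) lost their calls.

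In OE5 mock 8 genes were called (6 higher, 2 lower; 10 by DESeq2). SADHU3-2 was at 31.3 ± 11.9 CPM against 1.26 ± 0.448 in WT (4.62 ± 0.47, adjusted p = 3e-06) and AT5G35935 was higher (2.22 ± 0.27, adjusted p = 3.84e-05). QQS was higher (1.62 ± 0.28, adjusted p = 0.0132), a call lost without WT mock replicate 1 (0.203), without OE5 mock replicate 1 (0.0779) or 3 (0.0578), and without the 7 libraries low in CCA1 (0.139). The count fell from 8 to 3 and 4 without WT mock replicates 1 and 2, to 4 and 5 without OE5 mock replicates 1 and 3, and to 5 without the 7 libraries. With the compared groups alone it was 1, and AT5G35935 (0.285) and QQS (0.838) lost their calls.

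The gene lists that shifted between lines in mock plants had no called member by edgeR or DESeq2. In glyI2 mock the lists of photosynthesis (median −0.23, adjusted p = 0.00162), heat shock (−0.41, adjusted p = 0.00987), auxin (−0.19, adjusted p = 0.0304) and reactive carbonyl detoxification genes (−0.14, adjusted p = 0.0233) shifted down. Glucosinolate genes shifted up (0.25, adjusted p = 0.0209). Each of these had 0 members at unadjusted p under 0.05 and adjusted p = 0.649 with an estimated correlation. The photosynthesis list of glyI2 mock replicate 3, a library low in CCA1, differed from the other 2 of its group by −2.87 log2 units, and without the 7 such libraries the list had adjusted p = 0.109. In OE1 mock heat shock genes (−0.61, adjusted p = 0.0195) shifted down, and nitrate (0.58, adjusted p = 0.0195) and glucosinolate genes (0.44, adjusted p = 0.00836) shifted up. Each of these 3 had adjusted p = 0.709 with an estimated correlation, and 3, 2 and 2 members had unadjusted p under 0.05, with 1 nitrate gene higher when adjusted over the list alone. In OE5 mock abscisic acid (−0.22, adjusted p = 0.0324) and auxin genes (−0.41, adjusted p = 0.0324) shifted down. Ethylene (0.8, adjusted p = 0.0172) and phosphate starvation genes (0.6, adjusted p = 0.00112) shifted up. Each of these 4 had adjusted p = 0.709 with an estimated correlation, and 1, 1, 1 and 2 members had unadjusted p under 0.05.

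Clock genes set 7 libraries apart from the other 29. These were replicate 3 of WT NaCl, glyI2 mock, glyI2 NaCl, OE1 mock, OE1 NaCl, OE5 mock and OE5 NaCl. The morning gene CCA1 lay between −1.9 and 1.08 log2 CPM in them and between 4.24 and 6.31 in the others, and the light-harvesting gene LHCB2.2 lay between 3.6 and 5.86 against 9.41 to 11.6. Against the other 2 libraries of their group, LHY differed by −5.1 to −3.69 log2 units and the evening gene TOC1 by 1.4 to 1.62. PRR5 differed by 0.94 to 1.92, FKF1 by 1.68 to 2.85 and the iron transporter gene IRT1 by −9.38 to −2.94. Photosynthesis genes as a list differed by −2.9 to −1.69. Several counts and lists are also given without these 7 libraries.

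**Figure D2:**
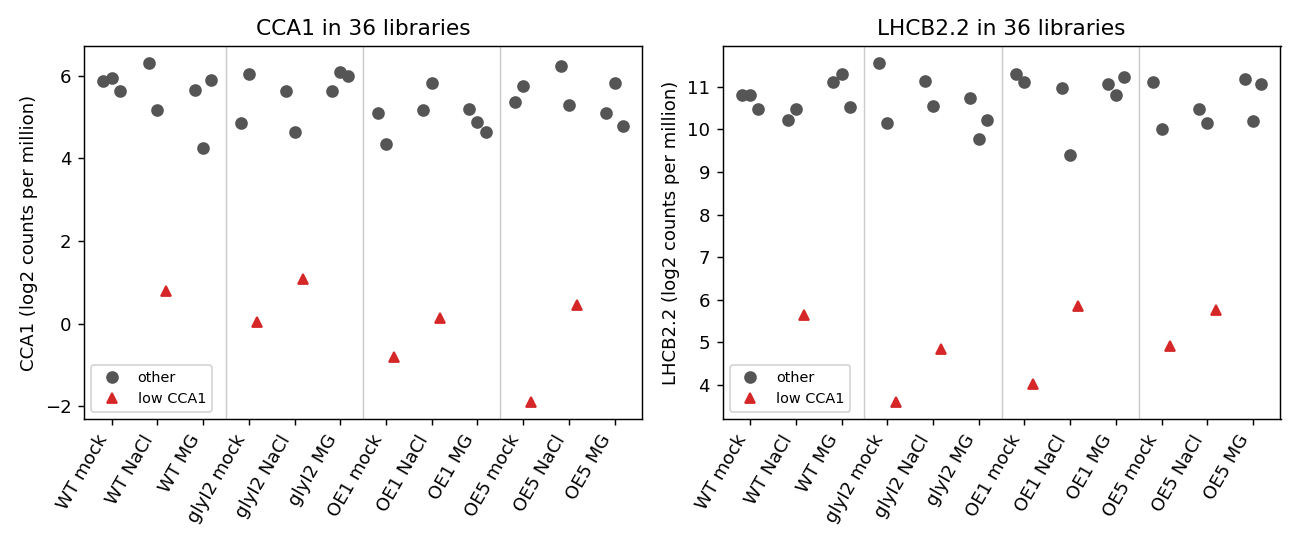
Levels of CCA1 and LHCB2.2 in log2 CPM; each symbol is 1 of 36 libraries. The 7 libraries with low CCA1 are drawn as triangles and are low in LHCB2.2 too.

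After NaCl, WT raised genes of abscisic acid signalling and dehydration and single genes of osmolyte synthesis. The phosphatase genes HAI2 (6.13 ± 0.85, adjusted p = 2.74e-05), HAI3 (5.02 ± 0.63, adjusted p = 8.04e-06) and ABI1 (1.44 ± 0.24, adjusted p = 0.000248), which act in abscisic acid signalling, rose. So did the abscisic acid catabolism gene CYP707A1 (2.21 ± 0.31, adjusted p = 2.82e-05). The dehydration proteins KIN1 (273 ± 80.1 CPM against 4.36 ± 1.83; 5.97 ± 0.79, adjusted p = 1.45e-05), RD29A (3.35 ± 0.61, adjusted p = 0.000695) and ERD10 (191 ± 42 against 47.8 ± 7.28; 2 ± 0.33, adjusted p = 0.000286) rose. P5CS1, which makes proline, went from 33.8 ± 16.8 to 379 ± 30.9 CPM (3.48 ± 0.59, adjusted p = 0.000334). The galactinol synthase genes GOLS4 (6.52 ± 0.76, adjusted p = 2.36e-06) and GOLS2 (4.44 ± 0.71, adjusted p = 0.000182) rose.

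Ion transport and nutrient genes moved in both directions in WT after NaCl. The sodium transporter gene HKT1 fell (−2.29 ± 0.33, adjusted p = 4.53e-05). The vacuolar exchangers NHX2 (1.65 ± 0.31, adjusted p = 0.000911) and CAX3 (1.67 ± 0.32, adjusted p = 0.00121) and the potassium transporter HAK5 (4.28 ± 0.83, adjusted p = 0.00133) rose. The nitrate reductase gene NIA1 fell from 801 ± 55 to 102 ± 20.8 CPM (−2.97 ± 0.34, adjusted p = 2.36e-06). The nitrate transporter gene NRT2.1 rose (4.25 ± 0.96, adjusted p = 0.0054). Cell wall genes EXPA10 (2.25 ± 0.3, adjusted p = 1.84e-05) and XTH19 (1.93 ± 0.41, adjusted p = 0.00339) rose. So did the dark-induced glucosidase gene DIN2 (3.71 ± 0.64, adjusted p = 0.000375). AT4G12545 had one of the largest falls (−3.83 ± 0.39, adjusted p = 4.32e-07).

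Genes that handle methylglyoxal and other carbonyls were in part raised by NaCl in WT. GLYI7, a glyoxalase I homologue, rose (3.52 ± 0.47, adjusted p = 1.83e-05). The aldo-keto reductase genes AKR4C9 (3.29 ± 0.67, adjusted p = 0.00211) and AKR4C8 (1.15 ± 0.16, adjusted p = 1.97e-05) and the glyoxalase III homologue DJ1E (0.88 ± 0.17, adjusted p = 0.00153) rose too. The detoxification genes CYP81D8 (2.04 ± 0.34, adjusted p = 0.000257), GSTF6 (1.81 ± 0.31, adjusted p = 0.000406) and UGT74E2 (1.83 ± 0.34, adjusted p = 0.000814) rose. The heat shock gene HSP22 went from 0.208 ± 0.141 to 15.2 ± 8.85 CPM (6.14 ± 0.65, adjusted p = 6.97e-07). The jasmonate genes CYP94B3 (2.71 ± 0.41, adjusted p = 7.37e-05) and LOX2 (2.77 ± 0.56, adjusted p = 0.00188) rose.

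Abscisic acid genes and dehydrins were the lists with the lowest p in WT after NaCl. Of 24 abscisic acid genes 16 rose and 8 did not pass the test (median 1.75, 17 adjusted over the list alone, adjusted p = 1.24e-17). Of 15 dehydrin and LEA genes 11 rose and 4 did not pass (median 3.82, 13 adjusted over the list alone, adjusted p = 2.97e-17). Of 20 jasmonate genes 8 rose and 12 did not pass (median 1.31, 11 up and 1 down adjusted over the list alone, adjusted p = 6.61e-08; adjusted p = 0.15 with an estimated correlation). Of 16 flavonoid genes 2 rose and 14 did not pass (median 1.57, 8 adjusted over the list alone, adjusted p = 0.000352; adjusted p = 0.427 with an estimated correlation). The rise of TT8 lost its call when any single library of the comparison was left out (0.0516 to 0.151) and without the 7 low-CCA1 libraries (0.101). Of 20 heat shock genes 4 rose, 1 fell and 15 did not pass (median 0.82, 4 up and 1 down adjusted over the list alone, adjusted p = 0.00214; adjusted p = 0.427 with an estimated correlation). The fall of HSFA7A lost its call without the 7 low-CCA1 libraries (0.103) and without any single library but WT mock replicate 2 (0.0511 to 0.18). The rise of HSP17.4 lost it without WT mock replicate 1 (0.0578) or 3 (0.0529) or WT NaCl replicate 2 (0.0613).

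Smaller shifts upward in WT after NaCl were found for 3 further lists. Of 38 reactive carbonyl detoxification genes 8 rose, 1 fell and 29 did not pass (median 0.05, 13 up and 3 down adjusted over the list alone, adjusted p = 0.0297; adjusted p = 0.427 with an estimated correlation). Of 12 antioxidant enzyme genes 2 rose and 10 did not pass (median 0.3, 4 up and 1 down adjusted over the list alone, adjusted p = 0.046; adjusted p = 0.427 with an estimated correlation). Of 11 phosphate starvation genes 1 rose and 10 did not pass (median 0.6, 2 adjusted over the list alone, adjusted p = 0.0167; adjusted p = 0.427 with an estimated correlation).

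Iron, auxin and cell cycle genes shifted downward in WT after NaCl. Of 15 iron genes 3 fell and 12 did not pass (median −0.73, 4 adjusted over the list alone, adjusted p = 0.00337; adjusted p = 0.385 with an estimated correlation). In this list 6 fell without the 7 libraries low in CCA1, in which IRT1 was low. The calls of F6H1 (0.0728), FRO2 (0.148) and IRT1 (0.127) were lost without WT mock replicate 1. Those of FRO2 and IRT1 were also lost without WT NaCl replicate 1, 2 or 3, at adjusted p from 0.0717 to 0.167. Of 28 cell cycle genes 1 fell and 27 did not pass (median −0.25, 0 adjusted over the list alone, adjusted p = 0.0203; adjusted p = 0.471 with an estimated correlation). The 23 auxin genes had 0 calls by edgeR and 0 by DESeq2, with 8 at unadjusted p under 0.05 and 0 adjusted over the list alone, and shifted down as a list (median −0.72, adjusted p = 0.0276; adjusted p = 0.427 with an estimated correlation).

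Other lists did not pass the list test in WT after NaCl, although single members moved. Of 26 glyoxalase genes 6 rose, 2 fell and 18 did not pass (median −0.01 but mean 0.28 and test direction up, 6 up and 3 down adjusted over the list alone, adjusted p = 0.21), with 4 up and 0 down without the 7 libraries. Members that rose or fell were 3 and 1 of 10 osmolyte genes (median 0.34, 3 and 3 adjusted over the list alone, adjusted p = 0.0655) and 3 and 1 of 16 ion transport genes (median 0.2, 3 and 1 adjusted over the list alone, adjusted p = 0.227). For cell wall expansion 3 rose and 2 fell of 17 (median −0.23 and mean −0.01 but test direction up, 4 and 3 adjusted over the list alone, adjusted p = 0.553). For nitrate 1 rose and 1 fell of 5 (median −0.18 and test direction down but mean 0.2, 1 and 1 adjusted over the list alone, adjusted p = 0.355). For sugar starvation 1 rose and 1 fell of 6 (median −0.8, 1 and 1 adjusted over the list alone, adjusted p = 0.385). Salicylic acid and defence genes had 2 of 19 higher (median 0.56, 2 up and 1 down adjusted over the list alone, adjusted p = 0.121), glucosinolate genes 1 of 15 higher (median −0.36, 1 adjusted over the list alone, adjusted p = 0.227) and photosynthesis genes 1 of 29 higher (median −0.6, 1 adjusted over the list alone, adjusted p = 0.0609). In WT NaCl replicate 3, 1 of the 7 low-CCA1 libraries, the photosynthesis list differed from the other 2 libraries of the group by −2.2 log2 units.

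In 7 further lists edgeR and DESeq2 each called 0 members in WT after NaCl. Unadjusted p was under 0.05 for 2 of 9 DREB, CBF and ZAT genes (median 0.68, list test adjusted p = 0.21), 1 of 8 endoplasmic reticulum folding genes (0.15, adjusted p = 0.281) and 3 of 9 ethylene genes (0.11, adjusted p = 0.21). The same count was 0 of 16 clock genes (−0.43, adjusted p = 0.268), 0 of 8 root hair genes (−0.05 with a mean of 0, adjusted p = 0.83), 3 of 6 endodermis genes (−0.25, adjusted p = 0.281) and 2 of 2 seed storage genes (2.65, adjusted p = 0.0609). Adjusted over the list alone, 2 ethylene and 2 seed storage genes rose and 0 genes of the other 5 lists were called.

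In total 1478 genes were called in WT after NaCl, 920 higher and 558 lower, and 1041 of them changed at least 2-fold. DESeq2 called 1843. The count fell to 843, 764 and 847 without WT mock replicate 1, WT mock replicate 3 and WT NaCl replicate 3. Without the 7 low-CCA1 libraries 1469 were called, of which 1101 were shared, and with the replicate number as a block 2300 were called.

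**Figure D3:**
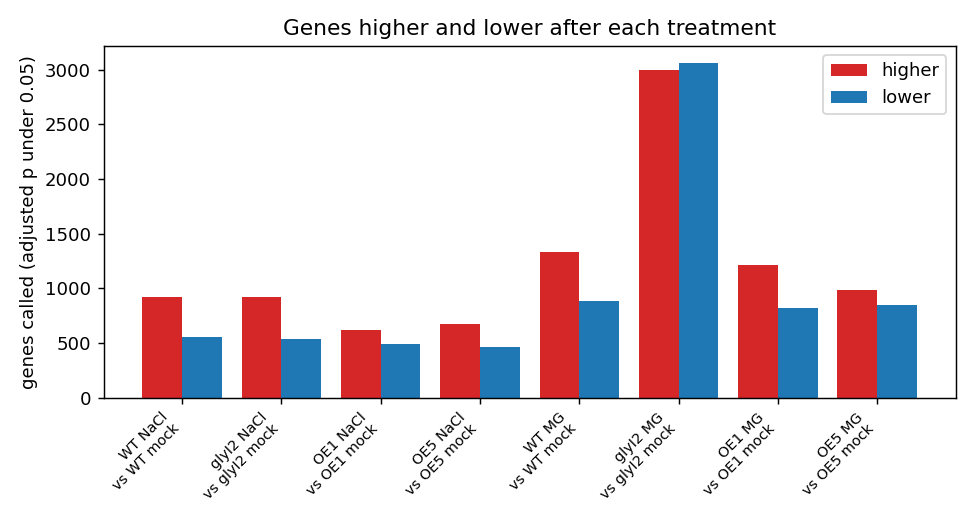
Number of genes called higher and lower (adjusted p under 0.05) for each treatment against the mock libraries of the same genotype, with 3 libraries per group. The bars of glyI2 after MG are the highest of the 8 pairs.

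The other genotypes answered NaCl with many of the same genes. HSP22 rose in glyI2 (7.31 ± 0.72, adjusted p = 2.69e-07), OE1 (7.27 ± 0.74, adjusted p = 4.9e-07) and OE5 (7.3 ± 0.71, adjusted p = 2.76e-07). AT1G73120 fell in glyI2 (−3.35 ± 0.45, adjusted p = 1.82e-05), OE1 (−3.57 ± 0.46, adjusted p = 1.67e-05) and OE5 (−3.33 ± 0.46, adjusted p = 2.88e-05), with the glyI2 call lost with the compared groups alone (0.0531). LTP4, a lipid transfer protein gene, rose in glyI2 (8.45 ± 1.81, adjusted p = 0.00315) and OE5 (8.04 ± 1.79, adjusted p = 0.00573), and LEA7 rose in glyI2 (7.87 ± 1.39, adjusted p = 0.00046). LTP4 also rose in WT (7.24 ± 1.72, adjusted p = 0.00788) and OE1 (7.38 ± 1.74, adjusted p = 0.0092). These 2 calls were lost without WT mock replicate 1 (0.0566) or 3 (0.0595) and without OE1 mock replicate 1 (0.0635).

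Abscisic acid genes rose in 17 of 24 cases in glyI2 (17 adjusted over the list alone, adjusted p = 4.77e-24), 14 in OE1 (20, adjusted p = 9.61e-25) and 15 in OE5 (21, adjusted p = 2.69e-26). Dehydrins rose in 13 of 15 cases in glyI2 (14 adjusted over the list alone, adjusted p = 3.9e-20), 10 in OE1 (14, adjusted p = 3.07e-19) and 12 in OE5 (15, adjusted p = 1.65e-21). Of 16 flavonoid genes 7 rose in glyI2 (median 1.82, 8 adjusted over the list alone, adjusted p = 3.53e-05; adjusted p = 0.369 with an estimated correlation), and 1 rose without the 7 low-CCA1 libraries. Of 20 heat shock genes 7 rose and 1 fell in glyI2 (median 1.42, 10 up and 1 down adjusted over the list alone, adjusted p = 1.22e-06; adjusted p = 0.272 with an estimated correlation).

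Counts after NaCl were 1462 in glyI2 (924 higher, 538 lower; 1853 by DESeq2), 1105 in OE1 (618 and 487; 1400 by DESeq2) and 1136 in OE5 (673 and 463; 1444 by DESeq2). The glyI2 count fell to 760 without glyI2 NaCl replicate 2. The OE1 count fell to 619 and 662 without OE1 mock replicates 1 and 2 and to 706 and 641 without OE1 NaCl replicates 1 and 2. The OE5 count fell to 608 without OE5 mock replicate 1 and to 538 without OE5 NaCl replicate 1. With the replicate number as a block the counts were 2224, 1786 and 1812, and with the compared groups alone 216, 500 and 293. Both replicate 3 libraries of the glyI2 comparison belong to the 7 low-CCA1 libraries, and without the 7 libraries the glyI2 count was 1498.

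In the 4 genotypes together 604 genes were called after NaCl, 370 higher and 234 lower in each. WT and glyI2 shared 1021 genes in the same direction and 0 in opposite directions, and their changes correlated with r = 0.81 over the genes tested. A difference in the NaCl response from WT was called for 0 genes in glyI2, OE1 and OE5 by edgeR, with 88, 230 and 162 genes at unadjusted p under 0.05 and 2, 1 and 0 genes by DESeq2. Without the 7 low-CCA1 libraries the counts were again 0, with 140, 792 and 168 at unadjusted p under 0.05. Lists that shifted in the NaCl response of glyI2 had no called member by edgeR or DESeq2 and 0 members at unadjusted p under 0.05. These were abscisic acid (median 0.38, adjusted p = 0.00245), heat shock (0.41, adjusted p = 0.0028), photosynthesis (0.51, adjusted p = 0.0028) and auxin genes (0.29, adjusted p = 0.00457), each with adjusted p = 0.796 with an estimated correlation. Without the 7 libraries the photosynthesis list had adjusted p = 0.772.

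After MG, WT raised many detoxification and heat shock genes. CYP71A12, which acts in camalexin synthesis, went from 1.2 ± 0.859 to 504 ± 122 CPM (8.72 ± 0.68, adjusted p = 2.31e-10). AT1G26380, an oxidoreductase of the indole pathway, went from 1.32 ± 0.617 to 428 ± 37.1 (8.34 ± 0.54, adjusted p = 1.19e-11), and the glutathione transferase gene GSTU25 went from 22 ± 3.95 to 641 ± 99.9 (4.87 ± 0.36, adjusted p = 7.84e-11). CYP81D8 (5.46 ± 0.38, adjusted p = 4.21e-11), UGT74E2 (5.08 ± 0.38, adjusted p = 1.39e-10), GSTU24 (3.71 ± 0.29, adjusted p = 2.31e-10) and the camalexin gene PAD3 (4.51 ± 0.33, adjusted p = 6.95e-11) rose. The calmodulin-like gene CML37 rose (8.2 ± 0.46, adjusted p = 1.39e-12). HSFA2 (5.66 ± 0.67, adjusted p = 3.27e-07), HSP17.8 (5.28 ± 0.71, adjusted p = 2.47e-06) and HSP17.6A (6.15 ± 0.87, adjusted p = 6.01e-06), which encode a heat shock factor and small heat shock proteins, rose.

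Transcription factor genes that rose in WT after MG were ZAT12 (4.41 ± 0.37, adjusted p = 7.03e-10), DREB19 (6.04 ± 0.54, adjusted p = 2.71e-09) and DREB2A (3.66 ± 0.47, adjusted p = 1.06e-06). The ethylene synthesis genes ACS2 (3.68 ± 0.42, adjusted p = 1.68e-07) and ACS6 (2.42 ± 0.46, adjusted p = 0.000298), the ethylene response factor ERF6 (3.6 ± 0.61, adjusted p = 7.44e-05) and the jasmonate catabolism gene CYP94B3 (5.79 ± 0.45, adjusted p = 2.31e-10) rose. CYP707A1 (2.17 ± 0.31, adjusted p = 5.46e-06), the dehydrin LTI30 (2.1 ± 0.32, adjusted p = 2.05e-05) and ANAC055 (2.86 ± 0.64, adjusted p = 0.00218) rose. The iron-linked coumarin gene F6H1 (2.98 ± 0.3, adjusted p = 1.87e-08), the stress factor BZIP60 (1.41 ± 0.28, adjusted p = 0.000511) and DHAR2 (1.87 ± 0.38, adjusted p = 0.000736) rose. Of the glyoxalase genes, DJ1E (1.91 ± 0.18, adjusted p = 4.68e-09) and DJ1A (0.55 ± 0.14, adjusted p = 0.00865) rose, the DJ1A call being lost with the compared groups alone (0.111).

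Root hair genes almost vanished in WT after MG. RHS19, a root hair peroxidase gene, went from 14.6 ± 4.3 to 0.174 ± 0.0823 CPM (−6.41 ± 0.56, adjusted p = 1.99e-09). PRP3 (−8.12 ± 0.88, adjusted p = 1.32e-07), COBL9 (−5.65 ± 0.66, adjusted p = 2.61e-07) and EXPA18 (−7.45 ± 0.87, adjusted p = 2.63e-07), which act in root hair walls, fell. EXT13 and EXPA17 had 0 counts after MG against 741 and 682 in mock, which is at least 230-fold and 206-fold lower against a floor of 3 counts. The endodermis genes CASP1 (−1.64 ± 0.34, adjusted p = 0.000985) and CASP2 (−1.61 ± 0.41, adjusted p = 0.00792) fell. So did the auxin genes YUC3 (−3.9 ± 0.64, adjusted p = 4.82e-05) and PIN2 (−1.77 ± 0.42, adjusted p = 0.0042). The ferric reductase gene FRO2 fell (−4.43 ± 1.16, adjusted p = 0.00947), a call lost without WT mock replicate 1 (0.0772) or WT MG replicate 3 (0.0506).

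Of 38 reactive carbonyl detoxification genes 29 rose in WT after MG and 9 did not pass the test (median 1.95, 31 adjusted over the list alone, adjusted p = 1.84e-36). Of 8 root hair genes 8 fell (8 adjusted over the list alone, adjusted p = 1.97e-20), with a median of −6.03 both as estimated and with the genes at the floor set to their bound. Of 9 DREB, CBF and ZAT genes 5 rose and 4 did not pass (median 2.07, 5 adjusted over the list alone, adjusted p = 1.09e-05). Of 20 heat shock genes 13 rose and 7 did not pass (median 2.88, 15 adjusted over the list alone, adjusted p = 1.66e-15; adjusted p = 0.0644 with an estimated correlation). Of 9 ethylene genes 5 rose and 4 did not pass (median 1.78, 5 adjusted over the list alone, adjusted p = 6.49e-06; adjusted p = 0.0904 with an estimated correlation). Of 24 abscisic acid genes 5 rose and 19 did not pass (median 0.83, 9 adjusted over the list alone, adjusted p = 0.000833; adjusted p = 0.442 with an estimated correlation).

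Other lists had few called members in WT after MG. Of 20 jasmonate genes 3 rose (4 adjusted over the list alone, adjusted p = 0.0143; adjusted p = 0.564 with an estimated correlation). Of 19 salicylic acid and defence genes 2 rose (2 adjusted over the list alone, adjusted p = 0.0258; adjusted p = 0.178 with an estimated correlation). Of 16 flavonoid genes 5 rose (7 adjusted over the list alone, adjusted p = 0.0329; adjusted p = 0.817 with an estimated correlation). Of 11 phosphate genes 1 rose (2 adjusted over the list alone, adjusted p = 0.0381; adjusted p = 0.608 with an estimated correlation). Of 28 cell cycle genes 1 fell (1 adjusted over the list alone, adjusted p = 0.0164; adjusted p = 0.65 with an estimated correlation). The fall of CYCB1;3 lost its call without WT mock replicate 1 (0.0934) or WT MG replicate 3 (0.0629). Of 6 endodermis genes 3 fell (3 adjusted over the list alone, adjusted p = 0.0329; adjusted p = 0.194 with an estimated correlation). The other 15 of the 27 lists did not pass the list test in WT after MG, and 3 of them are given here. Of 26 glyoxalase genes 2 rose and 24 did not pass (median 0.09, 2 adjusted over the list alone, adjusted p = 0.192). Of 15 dehydrins 1 rose (median 1.4, 1 adjusted over the list alone, adjusted p = 0.417). Of 15 iron genes 1 rose and 4 fell (median 0.45 and test direction up but mean −0.23, 1 and 4 adjusted over the list alone, adjusted p = 0.821).

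In WT 2215 genes were called after MG, 1331 higher and 884 lower, 1749 of them at least 2-fold, and DESeq2 called 2386. Without the 7 low-CCA1 libraries 2613 were called, 2160 of them shared.

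In glyI2 the MG response was broader than in WT. GSTU9 went from 6.48 ± 1.33 to 212 ± 36.6 CPM (5.03 ± 0.23, adjusted p = 3.74e-15) and UGT74E2 from 6.44 ± 1.93 to 812 ± 53.6 (6.98 ± 0.42, adjusted p = 2.7e-13). CYP81D8 (7.09 ± 0.41, adjusted p = 2.08e-13) and the transporter gene DTX4 (9.81 ± 0.67, adjusted p = 4.44e-12) rose. The transcription factors ZAT12 (4.98 ± 0.38, adjusted p = 2.9e-11), DREB19 (7.29 ± 0.57, adjusted p = 5.11e-11), DREB2B (5.98 ± 0.56, adjusted p = 1.97e-09) rose, as did WRKY33 (4.43 ± 0.74, adjusted p = 2.86e-05), WRKY40 (3.93 ± 0.65, adjusted p = 2.35e-05) and BZIP60 (3.41 ± 0.3, adjusted p = 4.87e-10). The ethylene genes ACS2 (5.92 ± 0.45, adjusted p = 3.84e-11), ACS6 (4.26 ± 0.49, adjusted p = 7.25e-08) and ERF1A (3.14 ± 0.34, adjusted p = 2.29e-08) rose. So did the camalexin gene PAD3 (3.6 ± 0.31, adjusted p = 4.58e-10) and the phosphatase gene HAI2 (4.89 ± 0.82, adjusted p = 2.94e-05). HSFA2 (5.66 ± 0.68, adjusted p = 1.76e-07) and HSP17.8 (5.5 ± 0.72, adjusted p = 7.4e-07) rose by about as much as in WT.

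In glyI2 after MG the replication genes MCM7 (−0.97 ± 0.2, adjusted p = 0.00033) and PCNA1 (−1.04 ± 0.26, adjusted p = 0.00257) and the cellulose synthase gene CESA1 (−0.81 ± 0.19, adjusted p = 0.00134) fell. RHS19 (−8.28 ± 0.62, adjusted p = 2.32e-11), CASP1 (−2.11 ± 0.35, adjusted p = 2.35e-05) and the dehydrin COR47 (−1.51 ± 0.27, adjusted p = 9.06e-05) fell too. The glyoxalase I homologue GLYI4 fell (−3 ± 0.43, adjusted p = 3.71e-06), whereas DJ1E (1.1 ± 0.17, adjusted p = 1.2e-05) and AKR4C8 (1.01 ± 0.16, adjusted p = 8.63e-06) rose.

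Of 38 reactive carbonyl detoxification genes 29 rose in glyI2 after MG (median 2.72, 32 adjusted over the list alone, adjusted p = 4.68e-29). Of 9 DREB, CBF and ZAT genes 7 rose (median 3.78, 7 adjusted over the list alone, adjusted p = 1.61e-08), and of 19 salicylic acid and defence genes 11 rose (median 1.5, 12 adjusted over the list alone, adjusted p = 5.51e-06). Root hair genes fell in 8 of 8 cases (median −7.01, also with bounds; 8 adjusted over the list alone, adjusted p = 4.27e-12). Of 20 heat shock genes 16 rose (median 3.05, 17 adjusted over the list alone, adjusted p = 4.66e-11; adjusted p = 0.12 with an estimated correlation). Of 9 ethylene genes 7 rose (median 3.14, 7 adjusted over the list alone, adjusted p = 3.55e-06; adjusted p = 0.0828 with an estimated correlation). Of 24 abscisic acid genes 15 rose (median 1.52, 17 adjusted over the list alone, adjusted p = 8.19e-05; adjusted p = 0.342 with an estimated correlation). Of 28 cell cycle genes 10 fell and 18 did not pass (median −0.67, 13 adjusted over the list alone, adjusted p = 0.000533; adjusted p = 0.558 with an estimated correlation). Of 17 cell wall genes 8 fell and 1 rose (median −0.81, 10 down and 2 up adjusted over the list alone, adjusted p = 0.0381; adjusted p = 0.558 with an estimated correlation). Of 26 glyoxalase genes 3 rose and 3 fell (median −0.13, 3 and 3 adjusted over the list alone, adjusted p = 0.775). The falls of GLYI6 and DLDH lost their calls without glyI2 MG replicate 2 (0.0783 and 0.11) and with the compared groups alone (0.127 and 0.134), among other settings. That of DLDH was also lost without the 7 low-CCA1 libraries (0.149).

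In glyI2 6056 genes were called after MG, 2993 higher and 3063 lower, 3604 of them at least 2-fold, with 6472 by DESeq2. The larger side was not the same in each setting, since 49.4% of the called genes were higher with TMM, 52.3% with RLE scaling and 51.9% by DESeq2. Without the 7 low-CCA1 libraries 6282 were called, 3426 higher and 2856 lower. WT and glyI2 shared 1756 genes in the same direction and 34 in opposite directions, and their changes correlated with r = 0.73.

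The libraries labelled OE1 and OE5 answered MG much as WT did. AT1G26380 rose in OE1 (8.56 ± 0.56, adjusted p = 7.07e-12) and OE5 (8.83 ± 0.56, adjusted p = 9.13e-12). CYP71A12 rose in OE1 (8.73 ± 0.69, adjusted p = 3.2e-10) and OE5 (8.61 ± 0.68, adjusted p = 3.62e-10). The extensin gene EXT10 fell in OE1 (−8.06 ± 0.88, adjusted p = 9.41e-08). Of 38 reactive carbonyl detoxification genes 25 rose in OE1 (median 2.01, 32 adjusted over the list alone, adjusted p = 1.64e-38) and 25 in OE5 (median 1.72, 33, adjusted p = 8.77e-38). Root hair genes fell in 8 of 8 cases in OE1 (median −5.96, also with bounds; 8 adjusted over the list alone, adjusted p = 1.66e-19) and in OE5 (median −6.43, also with bounds; 8, adjusted p = 3.06e-23). Heat shock genes rose in 13 of 20 cases in OE1 (14 adjusted over the list alone, adjusted p = 2.31e-12; adjusted p = 0.0878 with an estimated correlation) and in 12 in OE5 (15, adjusted p = 3.58e-16; adjusted p = 0.0557 with an estimated correlation).

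Counts after MG were 2031 in OE1 (1214 higher, 817 lower; 2216 by DESeq2) and 1831 in OE5 (983 and 848; 2014 by DESeq2). The OE5 count was 1139 with the compared groups alone. In the 4 genotypes together 1287 genes were called after MG, 732 higher and 555 lower in each. Changes correlated between WT and OE1 with r = 0.89, between WT and OE5 with r = 0.89 and between OE1 and OE5 with r = 0.91.

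The MG response itself differed between glyI2 and WT for many genes. GSTU9 (3.1 ± 0.29, adjusted p = 9.95e-08) and GSTU2 (3.27 ± 0.47, adjusted p = 5.6e-05) had higher responses in glyI2. So did the transporter gene DTX3 (3.82 ± 0.73, adjusted p = 0.00198), and the transcription factors ANAC102 (1.79 ± 0.39, adjusted p = 0.00556), DREB2B (3.91 ± 0.74, adjusted p = 0.00163), ZAT7 (3.84 ± 0.69, adjusted p = 0.000924) and BZIP60 (2 ± 0.39, adjusted p = 0.00229). The auxin genes GH3.3 (2.27 ± 0.48, adjusted p = 0.00469) and SAUR9 (4.62 ± 0.95, adjusted p = 0.00384) had higher responses too, as did the lipoxygenase gene LOX4 (2.37 ± 0.51, adjusted p = 0.00556), AT1G74870 (6.12 ± 0.7, adjusted p = 2.24e-06) and the NADH dehydrogenase gene NDB4 (5.56 ± 0.71, adjusted p = 9.99e-06).

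Other genes answered MG in WT and hardly or in the opposite direction in glyI2. CYP94B3 went from 1.82 ± 0.513 to 101 ± 11.7 CPM in WT and from 1.96 ± 0.766 to 4.12 ± 1.52 in glyI2 (difference −4.72 ± 0.57, adjusted p = 5.14e-06). F6H1 went from 20.5 ± 6.77 to 162 ± 53.2 in WT and from 20.2 ± 1.49 to 20.4 ± 7.54 in glyI2 (−2.96 ± 0.4, adjusted p = 2.62e-05). The phosphate transporter gene PHT1;1 went from 75.4 ± 17.5 to 195 ± 104 CPM in WT and from 91.3 ± 35.1 to 13.7 ± 4.86 in glyI2 (−4.11 ± 0.61, adjusted p = 8.54e-05). Responses were also lower in glyI2 for MLP328 (−4.95 ± 0.53, adjusted p = 8.52e-07), the germin-like gene GLP4 (−5.93 ± 0.74, adjusted p = 7.67e-06) and AT4G20390 (−4.76 ± 0.58, adjusted p = 5.14e-06).

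Of 38 reactive carbonyl detoxification genes 9 had a higher response in glyI2 and 29 did not pass (median 0.79, 12 up and 1 down adjusted over the list alone, adjusted p = 1.06e-07; adjusted p = 0.056 with an estimated correlation). The same held for 2 of 9 DREB, CBF and ZAT genes (median 0.68, 2 adjusted over the list alone, adjusted p = 0.000495; adjusted p = 0.056 with an estimated correlation) and 1 of 19 salicylic acid and defence genes (median 0.87, 5 adjusted over the list alone, adjusted p = 0.00215; adjusted p = 0.056 with an estimated correlation). It held for 2 of 9 ethylene genes (median 1.24, 4 adjusted over the list alone, adjusted p = 0.013; adjusted p = 0.539 with an estimated correlation). Of 11 phosphate starvation genes 2 had a lower response (median −1.05, 3 adjusted over the list alone, adjusted p = 0.00514; adjusted p = 0.539 with an estimated correlation). The 8 root hair genes had 0 calls by edgeR, 0 at unadjusted p under 0.05 and 1 by DESeq2.

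The response differed for 823 genes, 512 higher and 311 lower in glyI2, 720 of them at least 2-fold, with 1174 by DESeq2. The count fell to 534 and 514 without WT mock replicates 1 and 3 and to 514 without WT MG replicate 2, and it was 1110 without the 7 low-CCA1 libraries, 700 of them shared, and 1447 with the replicate number as a block. In 100 splits of these 12 libraries 7, the real one among them, called at least 823 genes. The other 6 kept the MG libraries parted by genotype and so repeat their difference, and the 92 splits that mixed them called at most 1 gene. The share of 7 in 100 therefore does not decide about chance. Of the 823 genes 477 had a larger rise in glyI2, 255 a larger fall, 86 a WT response that was smaller in glyI2, and 5 fitted none of these kinds. In OE1 and OE5 1 gene each differed from WT in its MG response, and in both it was GLYII4, with 3.15 ± 0.36 (adjusted p = 2.82e-05) in OE1 and 2.93 ± 0.36 (adjusted p = 0.000123) in OE5. With the compared groups alone GLYII4 lost the call in OE5 (2.93, adjusted p = 0.0735).

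NaCl and MG moved partly the same genes in WT. Both treatments raised 272 genes and lowered 188, and 28 genes moved in opposite directions. With the replicate number as a block 729 genes were shared. CYP707A1, CYP81D8, UGT74E2, CYP94B3 and DJ1E were among the genes raised by both. Independent lists would share 59 genes upward and 23.8 downward, and 20 simulations without treatment effects that kept the shared mock libraries gave 0. Without effects hardly any gene can be called, so that 0 was set by the simulation's design. It is no level of chance for genes that respond. The changes correlated with r = 0.41, against 0.5 from the shared controls alone, and the covariance was 0.33 against 0.08. The 3 mock libraries cannot be divided, so part of the excess may come from the shared controls.

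The 9 genes that differed in glyI2 without treatment are too few to compare with the MG response of WT. WT MG and glyI2 mock, each against WT mock, shared 0 genes by edgeR and 1 by DESeq2, where independent lists would share 0.321 upward and 0.17 downward and simulations gave 0 (r = 0.07 against 0.5, covariance 0.03 against 0.08). OE1 mock and OE5 mock shared 7 genes, 5 higher and 2 lower, among them GLYII4, AT5G35935 and MIR167a, and 0 with the compared groups alone by edgeR (8 by DESeq2 on the 36 libraries). Independent lists would share 0.00231 and 0.000289 and simulations gave 0 (r = 0.75 against 0.49, covariance 0.16 against 0.08). As above, that 0 was set by the simulation's design. OE1 mock and OE5 mock each hold a low-CCA1 library and WT mock holds none, a structure the simulations lack. AT5G35935 and MIR167a were also called in the same direction in glyI2 mock. The overlap, r and covariance therefore do not single out an effect shared by OE1 and OE5.

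A score compared the strength of each response between a line and WT. It was the mean log2 level of the raised genes minus that of the lowered genes, taken from genes called in the 2 genotypes not compared. The NaCl score of glyI2 differed from WT by 0.07 (3.57 against 3.5, exact permutation p = 0.755). That of OE1 differed by −0.14 (3.32 against 3.46, exact permutation p = 0.34) and that of OE5 by −0.11 (3.35 against 3.46, exact permutation p = 0.605). The MG score of glyI2 was taken over 880 raised and 675 lowered genes. It differed from WT by 0.49 (5.14 against 4.66, exact permutation p = 0.115, adjusted p = 0.69). Without glyI2 mock replicate 2 it differed by 0.73 and passed (exact permutation, adjusted p = 0.03). Mean scores after MG were 4.8 ± 0.11 in glyI2 and 4.4 ± 0.12 in WT. In mock they were −0.35 ± 0.43 and −0.26 ± 0.14. Relabellings that keep the MG libraries parted by genotype repeat the difference between those libraries, so the test also depends on the mock scores. The mock scores of glyI2 spread more widely (SD 0.43 against 0.14 in WT). Of the 12 fits that left out 1 library, only the 1 without glyI2 mock replicate 2 passed. With all libraries the score did not show a stronger MG response of glyI2 (exact permutation p = 0.115). It does not exclude one either. The MG scores of OE1 and OE5 differed by −0.07 (4.5 against 4.57, exact permutation p = 0.77) and −0.15 (4.11 against 4.26, exact permutation p = 0.555). The other 5 scores had an adjusted p = 0.77.

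**Figure D4:**
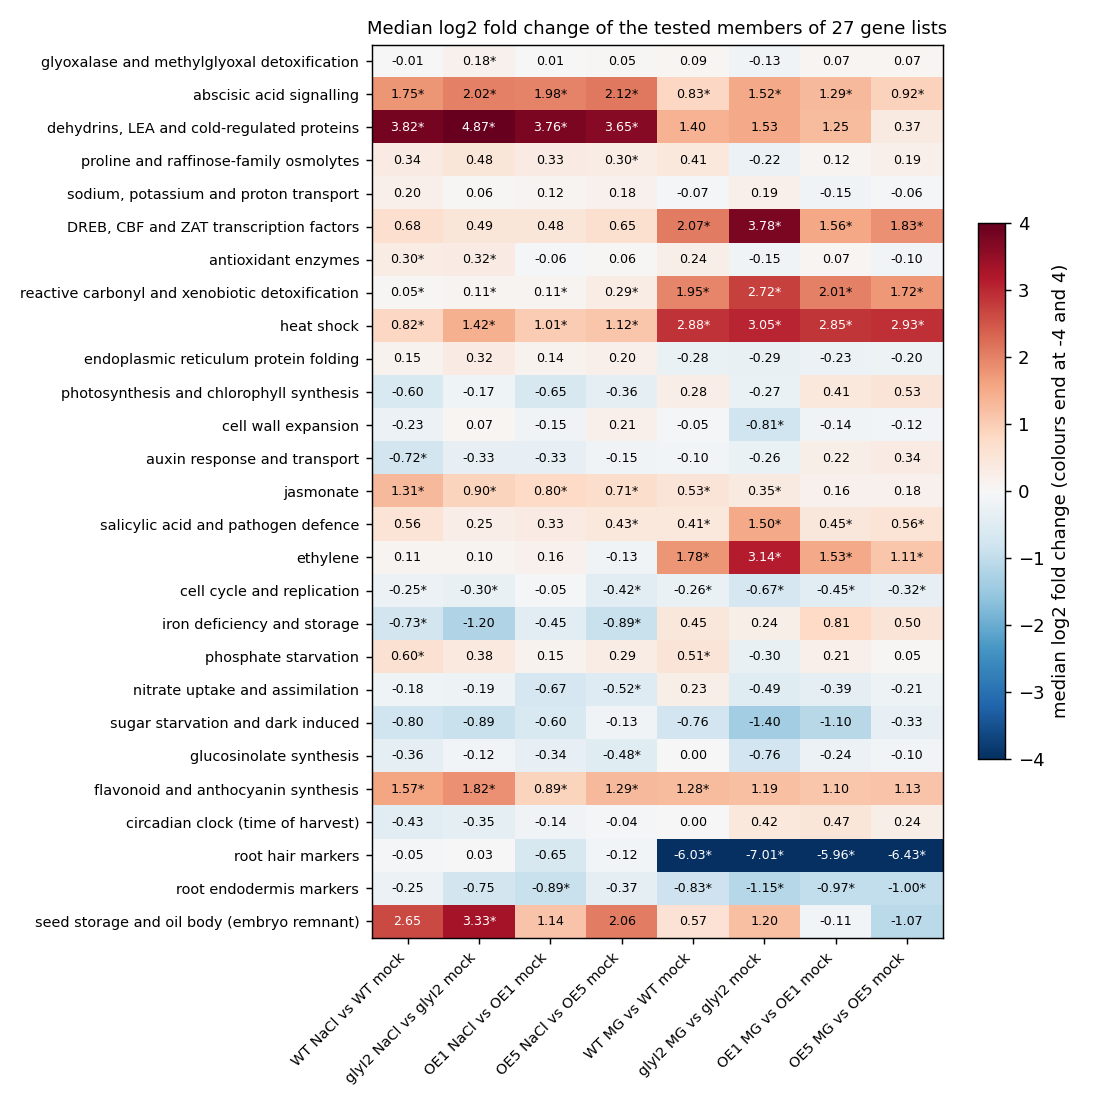
Median log2 fold change of the tested members of 27 gene lists in the 8 comparisons with mock; colours end at ±4 and an asterisk marks an adjusted p under 0.05 in the list test. Root hair genes are low in all 4 MG columns and abscisic acid genes and dehydrins are high in all 4 NaCl columns.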

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

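The tests of exchanged treatment labels, clock phase, gene length, shared reads, mislabelled OE1 and OE5 libraries and induction of the endogenous GLYII4 gene were chosen after the results were seen, as was the sorting of splits by whether the MG libraries stayed parted. The test of root tissue and the counts of splits were planned.

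A first group of results stood out because the response to MG differed between glyI2 and WT in the test of the difference itself. It covered 823 genes. Among them the log2 difference was 3.1 for GSTU9, 3.27 for GSTU2, 3.82 for DTX3, 1.79 for ANAC102, 3.91 for DREB2B, 3.84 for ZAT7, 2 for BZIP60, 2.27 for GH3.3, 4.62 for SAUR9, 2.37 for LOX4, 6.12 for AT1G74870 and 5.56 for NDB4. It was −4.11 for PHT1;1, −4.72 for CYP94B3, −2.96 for F6H1, −4.95 for MLP328, −5.93 for GLP4 and −4.76 for AT4G20390. As lists, DREB, CBF and ZAT genes (median 0.68), reactive carbonyl detoxification genes (0.79), salicylic acid and defence genes (0.87), ethylene genes (1.24) and phosphate starvation genes (−1.05) differed with the preset correlation. With an estimated correlation these 5 lists lost their call (adjusted p = 0.056, 0.056, 0.056, 0.539 and 0.539). ZAT7 stayed low in WT (0.984 ± 0.255 CPM in mock, 0.662 ± 0.345 after MG, n = 3) and went from 0.967 ± 0.383 to 9.74 ± 1.54 in glyI2, and DTX3 went from 1.8 ± 1.11 to 24.3 ± 5.12 in WT and from 2.22 ± 1.12 to 424 ± 63.9 in glyI2.

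Differences in 5 further genes were called but lost the call when single libraries were left out, with changes of the same direction. PBS3 (4.09, adjusted p = 0.0135) lost its call without WT mock replicate 2 (3.33, adjusted p = 0.0959). ACS2 (2.24, adjusted p = 0.0205) lost it without WT mock replicate 1 (0.0767), WT MG replicate 2 (0.0648) or glyI2 mock replicate 3 (0.0643), with log2 differences of 2.03 to 2.04. CYP707A1 (−1.68, adjusted p = 0.0188) lost it without WT mock replicate 3 (0.0504), glyI2 mock replicate 3 (0.0659), glyI2 MG replicate 1 (0.0539) or 3 (0.0666), with differences of −1.66 to −1.48. ERF2 (1.69, adjusted p = 0.0321) lost it without WT mock replicate 2 (0.104) or 3 (0.0514), WT MG replicate 2 (0.0876) or 3 (0.0667), glyI2 mock replicate 1 (0.0774) or 2 (0.0689), or glyI2 MG replicate 1 (0.0907) or 3 (0.0587), with differences of 1.45 to 1.76. GLYI6 (−0.71, adjusted p = 0.0284) lost it without WT mock replicate 1 (0.0745) or 3 (0.0852), WT MG replicate 2 (0.0976), glyI2 mock replicate 1 (0.0644) or 3 (0.0717), glyI2 MG replicate 1 (0.0559), 2 (0.109) or 3 (0.0926), without the 7 low-CCA1 libraries (0.0554), with RLE scaling (0.0563), with the compared groups alone (0.133) and without the expression filter (0.0566), with differences of −0.72 to −0.62.

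GLYII4 stood out because its response to MG differed from WT by 3.15 in OE1 and 2.93 in OE5. WT libraries under these labels were argued against, since 6 of the 6 MG libraries of these lines lay nearer the mock libraries of their own line than those of WT. This used the genes called in mock (11 in OE1 and 8 in OE5) without GLYII4 and GLYI2. The 2 lines shared 7 of the calls, and libraries were compared with WT and their own line only. An exchange between OE1 and OE5 was therefore not tested. Induction of the endogenous gene was argued against, since the higher of the upper 95% bounds of its change with MG in WT and glyI2 was 0.63. With the compared groups alone the difference was 3.16 in OE1 (adjusted p = 0.00175) and 2.93 in OE5, where it lost its call (adjusted p = 0.0735). What stays open, as a hypothesis, is that the transgene-derived GLYII4 transcript itself may rise with MG, for which the reads would have to be assigned to the transgene.

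The 7 libraries with low CCA1 form a second pattern. An exchange of mock and NaCl labels was argued against, since 7 of the 7 lay nearer their own treatment in the mean of the dehydrin genes. The 7 include libraries of both treatments, and CCA1 was at 4.24 log2 CPM or more in the other 29. Exchanged labels would therefore not account for low CCA1 in any case. A gene length bias of poor RNA was argued against for 3 of the 7, which lay between the other 2 libraries of their group in the correlation with gene length but had CCA1 lower than both by 4.4 to 7.26 log2 units. For the others it stays open, since 3 lay above both libraries of their group and 1 below both, where at least 2 on each side were needed to argue against it. Harvest at another clock phase stays open, because 5 of the 7 had evening genes over 1 log2 unit above their group with other morning genes below it, where all 7 were needed and fewer than 5 would have argued against it. The direction was the same in all 7, with evening genes 0.63 to 1.53 above and other morning genes −3.34 to −2.08. The libraries that missed the limit were glyI2 mock replicate 3 (0.94) and OE5 mock replicate 3 (0.63). The 7 libraries share replicate number 3, the labels name no batch or time of harvest, and no other explanation was tested.

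The fall of root hair genes after MG in the 4 genotypes is the last pattern weighed. Less root tissue in the MG libraries was argued against as the whole cause. The lowest median of 14 root genes outside hair cells over the 4 genotypes was −0.91, while the root hair medians ran from −7.01 to −5.96. A smaller loss of root tissue as a part of it stays open. The medians of the 14 genes were −0.91 in WT, −0.63 in glyI2, −0.69 in OE1 and −0.87 in OE5. Of these genes 0 were called higher in each, and 2, 5, 2 and 4 were called lower. Reads shared between repetitive cell wall genes were argued against, since 20 of 20 tests of the 5 members that are neither proline-rich nor extensin genes were called lower. A further hypothesis, which arose from these data and was not tested, is that MG may act on root hair cells or on the transcription of their genes. The number of root hairs was not measured here.

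Splits of the same libraries into other groups were counted for the 17 gene counts. The 6 libraries of a comparison of 2 groups make 10 splits, which cannot give a share under 0.05. The real count and the highest of the other splits were 1478 and 0 for WT NaCl, 1105 and 0 for OE1 NaCl, 1136 and 77 for OE5 NaCl, 2215 and 0 for WT MG, 6056 and 0 for glyI2 MG, 2031 and 0 for OE1 MG and 1831 and 0 for OE5 MG. In these 7 the real split was the 1 split with as many genes, as it was for mock plants, with 9 and 0 for glyI2, 11 and 0 for OE1 and 8 and 0 for OE5. Replicate numbers paired the libraries in OE5 NaCl, glyI2 MG and OE5 MG, and there the other 3 splits that part 3 pairs called 0 genes, while the 6 that part 1 pair called up to 77, 0 and 0. For glyI2 NaCl the real split called 1462 genes and another split called 5357, so 2 of 10 splits called as many. That split set glyI2 mock replicates 2 and 3 and NaCl replicate 3 against the rest, which points to a structure of these libraries apart from the treatment. The split goes with the correlation between gene length and a library's levels relative to the mean of the 36 libraries. That correlation ran from 0.172 to 0.385 in these 3 libraries and from −0.248 to −0.0392 in the rest. Over the 36 libraries this correlation went with the second principal component (r = 0.83). The TMM factors parted the same way, at 1.05 to 1.28 against 0.837 to 0.962. Both replicate 3 libraries among the 3 are also low in CCA1. These traits cannot be told apart here, and RNA quality was not measured.

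For the differences in response 100 of the 200 splits were counted, with genotypes exchanged within mock and within treated libraries. The NaCl responses called 0 genes by edgeR (88, 230 and 162 at unadjusted p under 0.05 in the real split, and 2, 1 and 0 genes by DESeq2). Any split reaches a count of 0, so the 100 of 100 splits that did so carry no information. Other splits called up to 5942 genes for glyI2, 11 for OE1 and 13 for OE5. The 5942 genes again point to a structure of the libraries. For the MG response of glyI2, 7 of 100 splits called at least the real 823 genes, with 1618 as the highest other, a share over 0.05. The other 6 of these 7 splits kept the glyI2 and WT libraries treated with MG parted and exchanged mock libraries. In the 92 splits that mixed the MG libraries the highest count was 1. Splits that keep the MG libraries parted repeat a difference between them, so the share can hardly fall under 0.05 and does not decide about chance. For OE1 and OE5 the real count was 1, and 8 of 100 splits called as many in each, with 13 as the highest other. That share is over 0.05 too and does not decide about chance for the same reason. The other 7 of these 8 splits kept the MG libraries parted, and in each line the 92 splits that mixed them called 0 genes by edgeR.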

How the results depend on the processing

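Leaving out the 7 low-CCA1 libraries, and for named genes and overlaps also the compared groups alone and no filter, were chosen after the data were seen, and the other alternatives were planned. With RLE scaling the share of called genes that were higher moved by less than 10 points in each comparison, from 62.2% to 70.1% at most (MG response of glyI2 against WT). The named genes gave 2406 values under alternatives, of which 2250 kept direction and side of the threshold and 0 reversed. Of the others 117 came from leaving out 1 library, 18 from the compared groups alone, 10 from leaving out the 7 libraries, 6 from RLE scaling and 5 from no filter, and DESeq2 and the replicate block ended no named call. Where a reason is not given here, the cause was not tested. With the replicate number as a block the counts were 2300 for WT NaCl, 2224 for glyI2 NaCl, 1786 for OE1 NaCl, 1812 for OE5 NaCl and 1447 for the MG response of glyI2, and WT NaCl and WT MG shared 729 genes. With the compared groups alone, and so fewer libraries behind each estimate of spread, the counts were 216 for glyI2 NaCl, 500 for OE1 NaCl, 293 for OE5 NaCl, 1139 for OE5 MG, 5 for glyI2 mock, 3 for OE1 mock, 1 for OE5 mock and 0 by edgeR for the MG response of OE5 against WT (114 at unadjusted p under 0.05), where edgeR and DESeq2 on the 36 libraries each called 1. With that setting OE1 mock and OE5 mock shared 0 genes by edgeR, against 7 by edgeR and 8 by DESeq2 on the 36 libraries. Without the 7 libraries OE5 mock had 5. DESeq2 called 2 genes in the NaCl response of glyI2, 1 in that of OE1 and 0 in that of OE5, where edgeR called 0 in each with 88, 230 and 162 at unadjusted p under 0.05, and it gave an overlap of 1 gene between WT MG and glyI2 mock. Of 459 list tests 112 passed, 21 with an estimated correlation, 126 with the block and 106 without the 7 libraries. Leaving out 1 library at a time, and so with fewer samples, gave 764 to 1172 for WT NaCl, 760 to 1890 for glyI2 NaCl, 619 to 1049 for OE1 NaCl, 538 to 1343 for OE5 NaCl, 1721 to 2019 for WT MG, 4507 to 5582 for glyI2 MG, 1616 to 1881 for OE1 MG, 1350 to 1741 for OE5 MG and 514 to 817 for the MG response of glyI2. The mock counts ran from 6 to 8 for glyI2, 4 to 10 for OE1 and 3 to 7 for OE5, and the difference in MG score between glyI2 and WT from 0.34 to 0.73, the last without glyI2 mock replicate 2 and passing its exact permutation test (adjusted p = 0.03).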

Other observations

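Phosphate starvation genes were followed across the OE1 and OE5 comparisons after their list values were seen. The list shifted up in OE5 mock (median 0.6 of 11 genes, adjusted p = 0.00112; adjusted p = 0.709 with an estimated correlation). It shifted down in the NaCl response of OE1 (−0.52, adjusted p = 0.0226; adjusted p = 0.809 with an estimated correlation) and of OE5 (−0.53, adjusted p = 0.00634; adjusted p = 0.774 with an estimated correlation), and in the MG response of OE5 (−0.57, adjusted p = 0.00483; adjusted p = 0.934 with an estimated correlation). No member was called by edgeR or DESeq2 in these 4 comparisons, with 2, 1, 0 and 0 genes at unadjusted p under 0.05. The differences in response share the mock libraries of WT and of the line, so these shifts are not independent of the one in mock.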
